A study of Danio rerio with 8 samples.

How the data were processed

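Total RNA from 4 eye tumors of zebrafish carrying an activated smoothened transgene (smoa1) and from 4 normal eyes of wild-type zebrafish was measured on 8 one-color Agilent oligonucleotide arrays; the labels give an age of 4 months. Per the labels and the file headers, the authors labeled the RNA with Cy3 and read the arrays with Agilent Feature Extraction 10.5.1.1. The deposited scanner files give the processed signal of each spot as an intensity, with the background subtracted and spatial trends removed within the array and no scaling between arrays. They also give the raw mean signal and the local background as an intensity, and other columns with flags of 0 or 1 for spots well above background, saturated or uneven. The deposited table of the series holds values on a log2 scale. Set against the scanner files array by array, these were log2 of the processed signal after a step that gave every array nearly the same quantiles (correlation across spots 0.999 to 1.00, column medians 7.19 to 7.20); the authors' text does not state that step.

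The comparison used the processed signals. Control spots were left out (1417), which left 43603 probes, of which 50 had 5 spots each that were averaged on the log2 scale. Spots flagged as uneven or as outliers among replicate spots were left out. Each array's log2 values were scaled by subtracting its 75th percentile over the spots that are not controls. A probe was kept if it was well above background on at least 4 of the 8 arrays, which left 36996 probes. Gene names came from the files, brought up to date by accession (27612 probes), by current symbol (1696) or by older symbol (921) with a gene table of assembly GRCz12tu that served for names alone, while 13374 probes kept the name of the file. Positions are those of the files, on build danRer6 (zv8), counted from 1. A gene with several kept probes was represented by the one with the highest mean signal over all 8 arrays; in 94 of 3802 such genes that passed, another probe passed in the other direction.

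Tumors and normal eyes were compared with limma 3.58.1 in R 4.3.3 (a linear model per probe with moderated variances), with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05, two-sided. Changes are log2 of tumor over normal eye, given with the standard error (SE) of that difference. Where a probe was not well above background on any array of 1 group, the change is given as a bound: the mean of the other group was set against that group's signal or, where higher, the lowest signal called well above background on the same array. The 31 gene lists were tested with limma's camera (preset correlation between genes 0.01, Benjamini-Hochberg over the lists, at least 3 measured members), with fry and with camera at an estimated correlation as alternatives. Camera asks whether a list's genes changed apart from the other genes, while fry asks whether they changed at all, so the calls of these tests answer different questions. The lists cover Hedgehog targets and components, the cell cycle, neural progenitors, glia, neurons, the cell types of the retina, lens, pigment cells, cornea, blood, immune cells, vessels, matrix, muscle, interferon, Notch and Wnt signaling, stress responses, glycolysis and ribosomal proteins. Each array's value for a list is the mean of its genes relative to the mean of the normal eyes.

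The tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule allowed any measured member of both Hedgehog lists to be named, and took the 10 largest rises and falls with the groups apart and the probe above background on all arrays, the 5 largest bounds in each direction, up to 4 members of each list with the smallest adjusted p and up to 2 members that did not pass. Probes without a name, or with a clone-type name (15815), were left out of the ranked parts. Genes named outside this rule are said to be so. After the results were seen, 1 measured Hedgehog target was left out of the text, the figure and the counts of named genes, for a reason that did not rest on its values; the list results include it.

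The alternatives were normexp background correction (offset 50), quantile normalization, scaling by the median, the deposited log2 table, no filter or a filter on all 8 arrays, uneven spots kept, an intensity trend with a robust prior, blocks for slide or replicate number, array weights, other thresholds, the mean of a gene's probes, other list tests, and each array left out. The arrays lay on slides 1 and 2, each with 2 tumors and 2 normal eyes, so both a slide block and each slide alone could be fitted. The tests were also run on simulated data built on the spread of these arrays: with 200 of 36946 probes changed between eye tumor and normal eye, limma recovered 44.0% of those changed 2-fold and 75.0% of those changed 4-fold, and 10 of the 129 probes called had not been changed. Far fewer probes were changed there than the 15331 that passed on the real arrays, and both groups were given the same spread. The recovered shares therefore need not hold for the real arrays. In 20 simulations of the lists, camera called the raised Hedgehog target list 20 times, and it called 0 lists where nothing had been changed. The simulated noise was drawn separately for each probe, so it held no correlation between genes. These runs therefore do not test the preset correlation of 0.01 on the real arrays, where the estimate for the Hedgehog targets was 0.375. Further steps ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9, and the reading of files in R with the package data.table, version 1.17.8. On the array 108 list members were not found by name, the Hedgehog receptor ptch1 and the pathway regulator kif7 among them, and no probe of nkx6.1 or dhh was kept.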

Results

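Gene expression was measured in 4 eye tumors of smoa1-transgenic zebrafish and in 4 normal eyes of wild-type zebrafish, all with a labeled age of 4 months. Smoa1 is an activated form of smoothened, the membrane protein that turns on Hedgehog signaling. On each array 82.0% to 85.6% of the spots that are not controls were well above background, the median processed signal was 123 to 176 intensity units and 0 spots were saturated. Slide 1 held normal eyes 1 and 3 with eye tumors 2 and 3, and slide 2 held normal eyes 2 and 4 with eye tumors 1 and 4. The labels do not say that the samples of a group came from separate fish, so the p-values measure only the spread between these samples, and the number of arrays limits the precision.

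The comparison of eye tumors with normal eyes asks which genes change when Hedgehog signaling is raised and a tumor forms, the subject of the series title. Transgene, tumor and strain go together in this design, so their effects cannot be told apart. Nor can a change within cells be told apart from a change in the cell types sampled. In the tumors, 9 of 10 measured Hedgehog target genes rose, with a mean log2 change of 2.14 over the list, as did 27 of 32 genes of S phase, 29 of 33 genes of mitosis and 27 of 32 markers of macrophages, microglia and neutrophils. Genes of the differentiated eye fell: 27 of 29 cone genes, 14 of 18 rod genes and 34 of 55 lens genes. The largest bounded rise was that of gh1 (growth hormone), at least 11538-fold higher in the tumors, and the largest fall was that of the adult globin ba2, whose log2 change was -8.48 ± 1.47 (SE, n = 4 per group).

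With limma, 15331 of 36996 probes passed an adjusted p of 0.05, 7326 higher and 8005 lower in the tumors. Of these, 7477 had changed at least 2-fold. With the slide as a block 14107 probes passed, and within slides 1 and 2 alone, with 2 arrays per group, 3268 and 283 passed. The tumors lay on one side of all normal eyes for 15561 probes, where chance gives 2.86% of probes. Among genes with a name, 5600 of 13172 passed (2886 higher, 2714 lower), and 264 of them had changed at least 8-fold, 210 higher and 54 lower. For 119 of the 120 genes given below or in the closing part as changed, all 4 tumors lay above or all below the 4 normal eyes. The exception was scn4ab. The rule required this of the largest rises and falls and took list members by smallest adjusted p, so the choice of genes largely set that count. Values are those of 1 representative probe per gene. Of the 69 of these genes with several kept probes, 14 had another probe that did not pass: arhgap27l, brf1a, ccnd1, cdc45, cdon, ckma, hbba1, hhip, mxc, mycb, opn1mw4, plp1a, rfx2 and vim, named after their values were seen.

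Correlations between arrays were 0.957 to 0.974 among tumors, 0.975 to 0.985 among normal eyes and 0.893 to 0.949 between the groups. Eye tumor 4 lay nearest to the normal eyes: on the first principal component, which held 65.1% of the variance, its coordinate was 42.4 against 111 to 143 in the other tumors and -109 to -100 in the normal eyes. Its cone genes averaged -0.54 relative to the normal eyes, against -2.63 to -2.03 in the other tumors, and its lens genes -0.10 against -2.08 to -1.04. Without eye tumor 4, 18043 probes passed.

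Hedgehog target genes rose as a list (mean log2 change 2.14, median 1.54, adjusted p = 0.000123; adjusted p = 0.525 with an estimated correlation). Many lists share this 0.525, because the Benjamini-Hochberg adjustment gave them a tied value. Before adjustment, camera at an estimated correlation gave p = 0.0830 for the Hedgehog targets, and the lowest of all lists was 0.0360 (Wnt targets). The mean over the Hedgehog targets was 1.70 to 2.73 in the 4 tumors relative to the normal eyes, 2.05 within slide 1 and 2.23 within slide 2, and its adjusted p with the slide as a block was 0.000143. With the members not above background in normal eyes set at their bound, the mean was 1.72 and the median 1.52. Adjusted over the list alone, 9 rose and 0 fell, as over all probes. The transcription factor nkx2.2a, which Hedgehog signals induce in the ventral neural tube, rose by 5.18 ± 0.28 (SE, n = 4 per group; adjusted p = 4.96e-05; chromosome 17, 40561801 to 40561860, danRer6). The floor plate regulator foxa2 was at least 17.1-fold higher, and nkx2.2b, a relative of nkx2.2a, at least 2.98-fold. The Hedgehog effector gli1 rose by 1.68 ± 0.35, the motor neuron and oligodendrocyte regulator olig2 by 1.61 ± 0.34 and the cyclin ccnd1 by 1.46 ± 0.19, with adjusted p of 0.00817, 0.00857 and 0.00162. The 3 other probes of ccnd1 changed by 1.40, 0.74 and 0.02, the last of which did not pass.

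Smaller changes were seen in the Hedgehog-binding protein hhip (0.62 ± 0.20, adjusted p = 0.0404) and the growth regulator mycn (0.40 ± 0.14, adjusted p = 0.0490). Both genes lay near the threshold. The call of hhip was lost without any array but normal eye 2 or eye tumor 2 (adjusted p up to 0.0991), and that of mycn without any array but eye tumor 3 or 4 (up to 0.116). When each array was left out, the log2 change was 0.45 to 0.71 for hhip and 0.30 to 0.48 for mycn. The cyclin ccnd2a did not pass, with -0.33 ± 0.28 and an adjusted p of 0.372. With normexp background correction the mean of the target list was 0.63, and nkx2.2b had a negative value that did not pass. After far local backgrounds were replaced the mean was 0.96, and nkx2.2b was no longer negative.

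**Figure D1:**
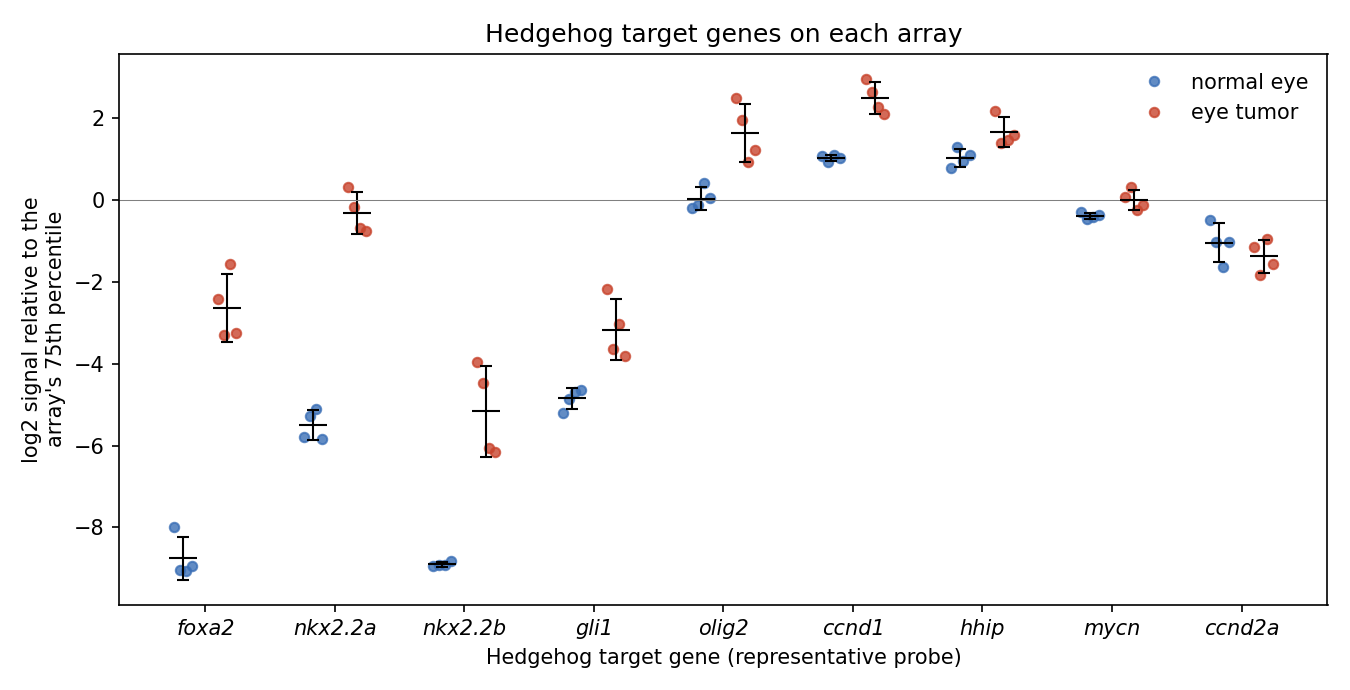
Log2 signal of the representative probe of 9 of the 10 measured Hedgehog target genes, relative to the array's 75th percentile, in the 4 normal eyes (blue) and the 4 eye tumors (red). Points are arrays, and bars give the mean and the SD; nkx2.2a differed by 5.18 between the group means and ccnd2a by -0.33.

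Of 17 measured components of the Hedgehog pathway, 8 rose, 3 fell and 6 did not pass, with the same counts adjusted over the list alone. As a list they did not pass (mean log2 change 0.37, adjusted p = 0.0980, and adjusted p = 0.525 with an estimated correlation), but did with fry (0.0227) and with normexp after far local backgrounds were replaced (0.0457). The mean was 0.23 within slide 1 and 0.51 within slide 2, and 0.25 without eye tumor 1. The signal transducer smo rose by 2.31 ± 0.37 (SE, n = 4 per group; adjusted p = 0.00338; chromosome 4, 14787182 to 14787241, danRer6) and by 3.05 at a second probe. The files do not say whether these probes also bind the transgene's transcript. The transcription factors gli2a (1.48 ± 0.17) and gli3 (0.83 ± 0.21), the ligand release factors scube2 (1.40 ± 0.20) and disp1 (0.66 ± 0.16), the co-receptor cdon (1.44 ± 0.29), the kinase stk36 (1.13 ± 0.25) and the cilium protein dzip1 (1.71 ± 0.16) rose as well. With normexp disp1 was at -0.44 and did not pass, but after far local backgrounds were replaced it was no longer negative. The ligands moved the other way: shha fell by 1.22 on the log2 scale, ihha fell by 1.67 and ihhb fell by 1.23, while shhb did not pass (-0.87, adjusted p = 0.210). The inhibitor sufu had a change of 0.00 ± 0.10.

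Genes of cell division rose together. In the S phase list 27 rose, 0 fell and 5 did not pass (29 rose and 1 fell adjusted over the list alone), with a mean log2 change of 1.11 and an adjusted p of 1.74e-08 (0.525 with an estimated correlation). Examples were the replication factors cdc45 (3.12 ± 0.26, and 0.58 at a second probe that did not pass) and rpa2 (1.37 ± 0.16). In the list of G2 and mitosis 29 rose, 0 fell and 4 did not pass (30 rose adjusted over the list alone), with a mean of 1.33 and an adjusted p of 8.98e-10 (0.525 with an estimated correlation). Among them were the mitotic cyclin ccnb2 (1.82 ± 0.29) and the kinetochore protein cenpf (1.48 ± 0.23). Cytosolic ribosomal protein genes rose by less, 65 up, 1 down and 12 not passed of 78 (67 and 1 adjusted over the list alone), with a mean of 0.43 and an adjusted p of 2.26e-14 (0.525 with an estimated correlation); rps6 rose by 0.70 ± 0.10 and rps23 by 0.63 ± 0.09. Within slides 1 and 2 the means were 1.07 and 1.12 for S phase, 1.25 and 1.41 for mitosis and 0.44 and 0.41 for ribosomal proteins, and in eye tumor 4 the first 2 lists averaged 0.69 each. With normexp background correction the mean of the mitosis list was 0.78.

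Neural stem and progenitor genes rose as a list, with 17 up, 5 down and 17 not passed of 39, the same adjusted over the list alone (mean log2 change 0.72, adjusted p = 0.00901, and 0.525 with an estimated correlation; means 0.77 and 0.67 within slides 1 and 2). The progenitor regulator sox2 rose by 1.85 ± 0.20, the radial glial fatty acid binding protein fabp7a by 2.75 ± 0.31 and the intermediate filament vim by 1.17 ± 0.12. In the oligodendrocyte list 3 of 11 rose and 8 did not pass (2 rose adjusted over the list alone; mean 1.03, adjusted p = 0.0128, and 0.525 with an estimated correlation). The genes that rose were nkx2.2a, olig2 and the myelin gene plp1a. The first 2 of these are also in the Hedgehog target list. The gene plp1a rose by 1.01 ± 0.34 and lost its call without any array but eye tumor 3 or 4 (adjusted p up to 0.105). The myelin gene mpz did not pass (0.81, adjusted p = 0.129). This list's mean was 0.95 within slide 1, where it did not pass (adjusted p = 0.0837), 1.12 within slide 2 and 0.67 with normexp background correction. Targets of Wnt signaling rose as a list, 7 up, 1 down and 5 not passed of 13 (9 and 1 adjusted over the list alone; mean 0.55, adjusted p = 0.0201, and 0.525 with an estimated correlation). The growth regulator mycb rose by 0.73 ± 0.13. The Wnt call was lost without eye tumor 3 or 4 (adjusted p = 0.0599 and 0.0655) and within slide 1 (mean 0.39, adjusted p = 0.0729; 0.57 within slide 2). The mean was 0.31 with no filter and 0.16 with normexp.

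Several lists of the nervous system did not pass as lists while single genes in them changed. Among genes of astroglia and Müller glia 7 rose, 3 fell and 6 did not pass, the same adjusted over the list alone (mean log2 change 0.80, median 0.10, adjusted p = 0.0980). The list passed with fry (adjusted p = 0.000409), with normexp (mean 0.58, adjusted p = 0.000756) and with normexp after far local backgrounds were replaced (0.54 and 0.0358). The calcium-binding protein s100b was up by 4.90 ± 0.28 and the carbonic anhydrase ca14 by 2.07 ± 0.19. Among neuron genes 5 rose, 8 fell and 12 did not pass, the same adjusted over the list alone (mean -0.05, which turned to 0.02 under quantile normalization, adjusted p = 0.510). The mean of the neuron list was 0.67 in eye tumor 2 and -0.55 to -0.10 in the other tumors. The growth cone protein gap43 rose by 3.67 ± 0.44, while the ribbon synapse protein cplx4a fell by 2.13 on the log2 scale. Notch signaling genes numbered 10 up, 3 down and 9 not passed of 22, the same adjusted over the list alone (mean 0.42, adjusted p = 0.0857, and 0.0386 without eye tumor 3). This list also passed with the mean of a gene's probes (0.0411), with the filter on all 8 arrays (0.0432) and with normexp, where the adjusted p was 0.01996 without the replacement and 0.0336 with it. The Notch target her4.1 rose by 2.77 ± 0.41. In retinal ganglion cell genes 5 rose, 1 fell and 10 did not pass, the same adjusted over the list alone (mean 0.26, adjusted p = 0.352), while the transcription factor tbr1b rose by 1.58 ± 0.24. Without eye tumor 2, whose mean was 1.04, the mean of the list was -0.00165. With an estimated correlation the adjusted p of these lists was 0.525 or higher.

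Photoreceptor genes fell. Of 29 cone genes 27 fell, 1 rose and 1 did not pass (28 fell and 1 rose adjusted over the list alone; mean log2 change -1.89, adjusted p = 1.71e-07, and 0.525 with an estimated correlation). Among them were the green opsins opn1mw2 (-2.25 ± 0.33) and opn1mw4 (-1.16 ± 0.20). The gene that rose was the red opsin opn1lw1 (1.72 ± 0.29). Of 18 rod genes 14 fell and 4 did not pass (16 fell adjusted over the list alone; mean -1.34, adjusted p = 8.82e-05, and 0.525 with an estimated correlation). Among them were the rhodopsin kinase grk1a (-2.05 ± 0.36) and the transducin subunit gngt1 (-1.50 ± 0.31). The list of photoreceptor regulators and the visual cycle had 4 of 12 fall, the same adjusted over the list alone (mean -0.83, adjusted p = 0.0409, and 0.525 with an estimated correlation). Of these, impdh1a was at -2.50 ± 0.54 and retinoschisin (rs1a) at -1.81 ± 0.31. That call was lost without normal eye 2 or eye tumor 1 or 2 (adjusted p = 0.0606, 0.0767 and 0.0697) and within slide 2 (-0.82, adjusted p = 0.0587). It was also lost with quantile normalization (-0.70, adjusted p = 0.0834), with the deposited table (0.0754), with no filter (0.0511) and with normexp (0.190). Of 17 bipolar cell genes 9 fell and 8 did not pass, the same adjusted over the list alone (mean -0.81, adjusted p = 0.00779, and 0.525 with an estimated correlation). The calcium-binding protein cabp5b changed by -1.53 ± 0.32. Horizontal and amacrine cell genes did not pass as a list, with 3 up, 8 down and 13 not passed, the same adjusted over the list alone (mean -0.29, adjusted p = 0.0980, and -0.43 with adjusted p = 0.0222 without eye tumor 2; adjusted p = 0.655 with an estimated correlation). The transcription factor onecutl changed by -1.09 ± 0.11. Within slides 1 and 2 the means were -2.13 and -1.65 for cones, -1.33 and -1.36 for rods, -0.84 in slide 1 for the regulators, and -0.93 and -0.69 for bipolar cells.

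Lens genes fell in 34 of 55 cases and 21 did not pass (44 fell and 1 rose adjusted over the list alone; mean log2 change -1.09, adjusted p = 2.95e-07, and 0.525 with an estimated correlation). The alpha crystallins cryaa (-1.31 ± 0.29) and cryaba (-1.26 ± 0.29) were among those that fell. Genes of the cornea and surface epithelium fell as a list, 20 down, 2 up and 9 not passed of 31 (21 down and 2 up adjusted over the list alone; mean -1.19, adjusted p = 0.000184, and 0.525 with an estimated correlation). The keratin krt96 was down (-2.81 ± 0.59), while the genes that rose were the simple epithelial keratins krt18a.1 (1.31 ± 0.14) and krt8 (0.95 ± 0.15). Within slides 1 and 2 the means were -1.08 and -1.09 for the lens and -1.43 and -0.93 for the cornea. Retinal pigment epithelium genes (3 up, 4 down, 7 not passed; 4 up and 5 down adjusted over the list alone; mean -0.13, adjusted p = 0.975) and pigment cell genes (3 up, 5 down, 7 not passed; 4 up and 5 down adjusted over the list alone; mean 0.26, adjusted p = 0.828) did not pass as lists. The retinoid isomerase rpe65c rose by 2.53 ± 0.19 and the melanosome protein pmelb by 3.60 ± 0.57. Without eye tumor 2 the mean of the first was 0.12 and of the second 0.59.

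Markers of macrophages, microglia and neutrophils rose in 27 of 32 cases and 5 did not pass (28 rose adjusted over the list alone; mean log2 change 2.11, adjusted p = 8.25e-11; adjusted p = 0.525 with an estimated correlation). The lysozyme lyz rose by 2.32 ± 0.20, the myeloid regulator spi1b by 3.08 ± 0.35 and the leukocyte actin-binding protein coro1a by 2.06 ± 0.25. The mean was 2.16 within slide 1, 2.06 within slide 2 and 1.48 in eye tumor 4. Lymphocyte and antigen presentation genes did not pass as a list, with 2 up, 3 down and 17 not passed (2 up and 2 down adjusted over the list alone; mean 0.05, adjusted p = 0.510, and -0.27 with normexp). The chemokine receptor cxcr4b rose by 1.00 ± 0.12. In the interferon list 4 rose, 1 fell and 10 did not pass, the same adjusted over the list alone (mean 1.29, adjusted p = 0.0419; adjusted p = 0.603 with an estimated correlation). The ubiquitin-like protein isg15 rose by 4.41 ± 1.04 and the GTPase gbp1 by 3.19 ± 0.66. The gene that fell was mxc (-0.35 ± 0.09), which had higher values at its other probes (1.57 and 1.35, not passed) and lost its call without normal eye 2, 3 or 4 or eye tumor 1 (adjusted p up to 0.0648).

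Normal eye 1 had a mean of 2.19 in the interferon list, above all 4 tumors (0.80 to 1.57), and the other normal eyes had -0.91 to -0.57. Without it the mean change was 2.02 (adjusted p = 6.78e-06). The interferon call was lost without normal eye 2, 3 or 4 (adjusted p = 0.0686, 0.0899 and 0.0881), without eye tumor 1, 3 or 4 (0.0607, 0.0814 and 0.104), with array weights (0.0541), with fry (0.151) and within slide 1, which holds normal eye 1 (mean 0.49, adjusted p = 0.391; 2.09 within slide 2).

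Red blood cell genes fell as a list, with 15 down, 2 up and 5 not passed of 22 (17 down and 3 up adjusted over the list alone; mean log2 change -1.73, adjusted p = 0.000307, and 0.525 with an estimated correlation). Adult globins fell by unequal amounts: hbaa2 changed by -6.65 ± 0.66, hbba2 by -4.65 ± 0.75, hbaa1 by -3.08 ± 0.50 and hbba1 by -2.28 ± 0.50. Other probes of hbba2 changed by -4.96 and -9.94. The probe that the files name ba2 changed by -8.48, with an SD of 3.39 in the tumors against 0.33 in the normal eyes, and a second one by -12.05. The lists give ba2 as an older name of hbba2, but the files give its probes other transcript records, so they were not merged with hbba2 and were left out of the list. The genes hbaa1 and hbba1 were singled out after their values were seen. The erythroid regulator gata1a changed by -2.76 ± 0.43 and the red cell carbonic anhydrase cahz by -1.37 ± 0.20. Genes of blood vessel endothelium fell as a list, 14 down, 2 up and 9 not passed of 25, the same adjusted over the list alone (mean -0.35, adjusted p = 0.0128, and 0.525 with an estimated correlation). The junction protein cdh5 changed by -1.17 ± 0.15 and the receptor tek by -1.12 ± 0.18. The genes that rose were the barrier claudin cldn5a (3.84 ± 0.22) and the apelin receptor aplnra (2.61 ± 0.39). The endothelial call was lost within slide 1 (-0.39, adjusted p = 0.0648; -0.30 within slide 2) and with normexp (adjusted p = 0.109). For red cells the means within slides 1 and 2 were -1.92 and -1.54.

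Skeletal muscle genes fell as a list, 13 down, 3 up and 23 not passed of 39, the same adjusted over the list alone (mean log2 change -0.89, adjusted p = 0.00110; adjusted p = 0.540 with an estimated correlation). The creatine kinase ckma changed by -1.39 ± 0.17 and the myosin myhc4 by -1.56 ± 0.30, while the light chain mylpfb rose by 1.32 ± 0.21. The muscle call was lost within slide 1 (-0.48, adjusted p = 0.113; -1.31 within slide 2) and with fry (0.0545). Genes of glycolysis and hypoxia fell as a list, 15 down, 1 up and 19 not passed of 35, the same adjusted over the list alone (mean -0.57, adjusted p = 0.00155; adjusted p = 0.525 with an estimated correlation). The glycolytic enzymes eno1b (-1.35 ± 0.23), aldocb (-1.02 ± 0.19) and hk1 (-0.83 ± 0.14) were among them. Their mean was -0.36 within slide 1 and -0.78 within slide 2. Matrix and fibroblast genes were split, 10 up, 12 down and 18 not passed, the same adjusted over the list alone (mean -0.21, adjusted p = 0.975). Fibronectin fn1a rose by 2.06 ± 0.26. Without eye tumor 2 the mean was -0.00713. In the p53 list 10 rose, 5 fell and 6 did not pass, the same adjusted over the list alone (mean 0.27, adjusted p = 0.0980; 0.0235 with fry, and 0.000754 and 0.0224 with normexp without and with far local backgrounds replaced). The p53 target phlda3 rose by 1.37 ± 0.16. Immediate early and heat shock genes had 8 up, 8 down and 13 not passed (8 up and 9 down adjusted over the list alone), with a mean of 0.13, a median of -0.11 and an adjusted p of 0.975. No list called with camera's preset correlation held with an estimated one.

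**Figure D2:**
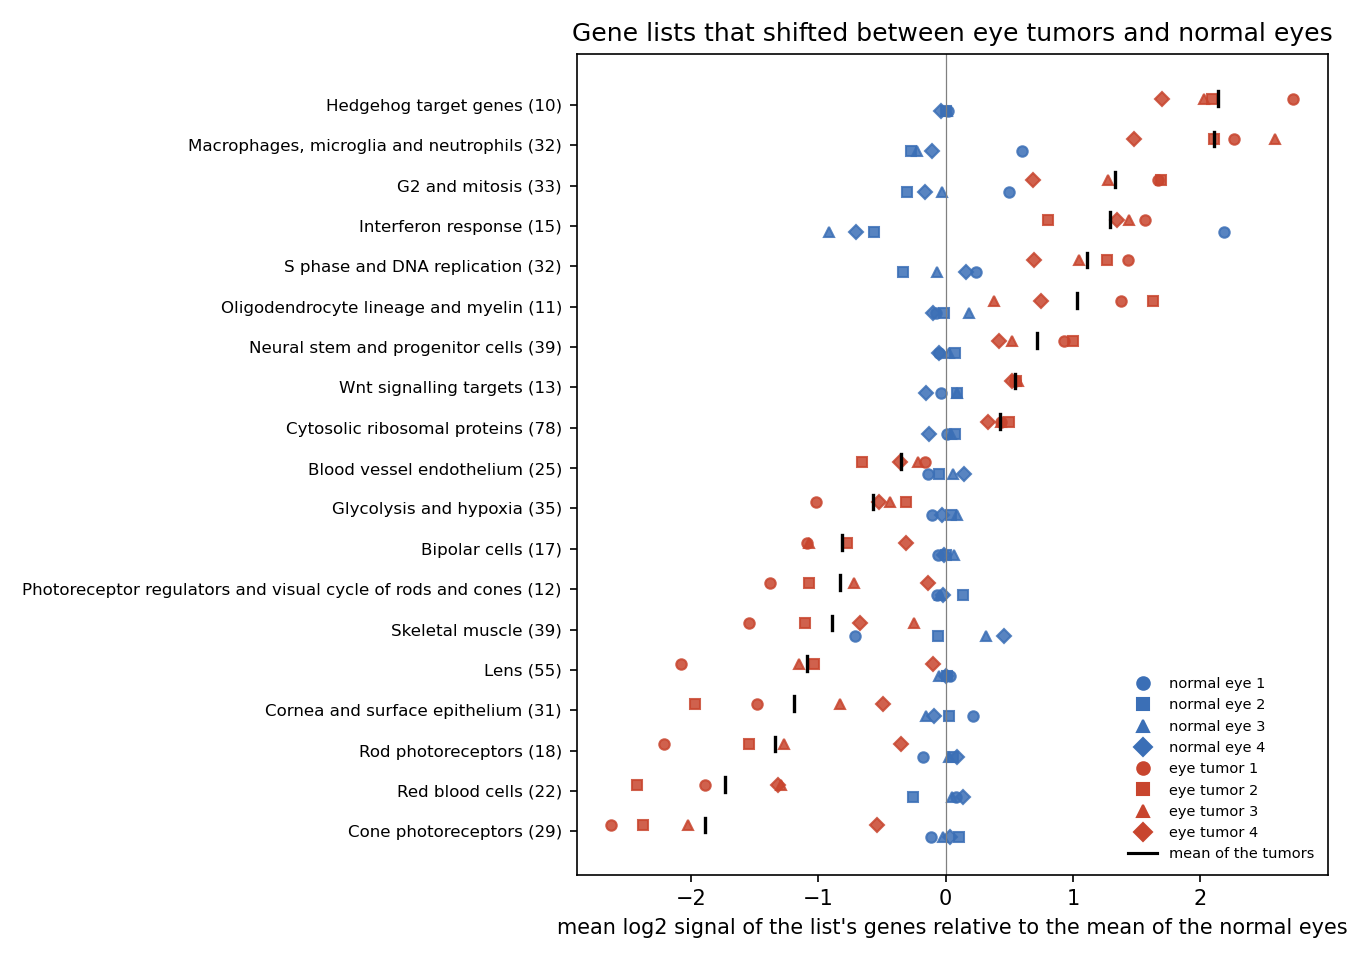
Mean log2 signal of each of the 19 gene lists that passed, relative to the mean of the 4 normal eyes, on each array; blue symbols are normal eyes, red symbols are eye tumors, the symbol gives the replicate number and the black bar the mean of the tumors. The number of measured genes is given beside each list; the tumors' mean was 2.14 for Hedgehog targets and -1.89 for cones, and eye tumor 4 lay nearest to the normal eyes for cones and lens.

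The genes with the largest rises among those above background on all arrays included the neurohypophyseal hormone genes avp (8.34 ± 0.79 on the log2 scale, SE, n = 4 per group; adjusted p = 0.000490; chromosome 8, 1106060 to 1106119, danRer6) and oxt (6.42 ± 0.40). The leptin gene lepb rose by 8.26 ± 0.53, the forebrain transcription factor dlx1a by 6.90 ± 0.51, the regulator of motile cilia foxj1a by 6.44 ± 0.46, the neural transcription factor sox1a by 5.95 ± 0.50 and the brain aromatase cyp19a1b by 5.63 ± 0.40. Next came tnfaip2b (5.62 ± 0.75), the type I interferon ifnphi3 (5.59 ± 0.39) and plekhs1.3 (5.53 ± 0.74). Among genes not above background in any normal eye, gh1 was at least 11538-fold higher (chromosome 3, 18229999 to 18232264, danRer6). The otolith matrix gene stm was at least 285-fold higher, ggact.2 at least 230-fold, the relaxin-like peptide gene rln3a at least 219-fold and the forebrain transcription factor sp9 at least 161-fold.

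After ba2 and hbaa2, the largest falls were those of the sterol 12-alpha-hydroxylase gene cyp8b1.3 (-4.82 ± 0.31, adjusted p = 0.000104; chromosome 2, 2583295 to 2583354, danRer6) and of hbba2. The transcription factor gene brf1a changed by -4.47 ± 0.22 at its brightest probe, but by -0.47 and, past the threshold, by 1.18 at its other probes. The sulfotransferase gene sult3st3 changed by -4.20 ± 1.17, tdrd1, a gene of the germline piRNA pathway, by -4.13 ± 0.63, cyp8b1.2, the neighbor of cyp8b1.3, by -4.06 ± 0.30, mgarpb by -4.04 ± 0.93 and the chemokine gene ccl38a.5 by -3.92 ± 0.38. The call of sult3st3 was lost without normal eye 2, 3 or 4 or eye tumor 1 (adjusted p up to 0.0599). Among genes not above background in any tumor, the kinase gene grk5 was at least 6.19-fold lower, mettl21cb at least 5.79-fold, gfral at least 5.14-fold, the connexin gene gjb9a at least 4.87-fold and the prostaglandin D synthase gene ptgdsa at least 4.64-fold.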

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

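No test of this part was chosen after the result was seen. In each group of 4 arrays, the array farthest from the others was compared with the group's range by Dixon's 95% limit, and 16 of the 330 groups examined (gene lists and named genes) held a far array. Chance gives about 1 in 20 groups, which is close to that share.

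The widest gap on the log2 scale was that of the interferon list in normal eye 1, 2.19 relative to the mean of the normal eyes, while the other normal eyes lay from -0.91 to -0.57; its share of the range was 0.888, and the highest share was that of ihha (0.974). A far array was also found in 5 further lists: astroglia and Müller glia in eye tumor 1 (0.92, with the other tumors at 0.74 to 0.77), matrix and fibroblasts in eye tumor 2 (-0.81), horizontal and amacrine cells in normal eye 3 (0.10), pigment cells in normal eye 4 (0.0736) and, from a list written after the first look at the data, the telencephalon in normal eye 3 (0.16).

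Among single genes, given as log2 signal relative to the array's 75th percentile, the far value was in a normal eye for ccl38a.5 (-2.45 in normal eye 1), cyp8b1.2 (-1.93 in normal eye 3), cyp8b1.3 (-1.67 in normal eye 3), mgarpb (1.41 in normal eye 4) and the red opsin opn1lw1 (2.33 in normal eye 1, with the others at 3.32 or higher). For foxa2 (-7.98 in normal eye 1), hoxb5b (-6.94 in normal eye 3) and stm (-7.75 in normal eye 2) the far value lay in a group where the probe was not above background. In the tumors the Hedgehog ligands ihha (-3.93 in eye tumor 2, with the others at -2.72 to -2.69) and ihhb (-2.35 in eye tumor 3, with the others at -2.98 to -2.93) held a far array. No explanation was tested for any of these values.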

How the results depend on the processing

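The fits within each slide and the normexp fit with far local backgrounds replaced were chosen after the result was seen; the other settings were planned. The number of probes that passed (15331) stayed between 11022 and 18227 when each array was left out in turn (11022 to 18043), with quantile normalization (15580, of which 14850 were shared), scaling by the median, the deposited table, another filter, uneven spots kept, an intensity trend, array weights and the slide block (14107, 13871 shared). With normexp background correction 2860 passed, the median of all probes shifted by -0.39 and 36.6% of the probes that passed were higher, against 47.8%. On normal eye 1, where 16 spots had a very high local background, normexp had fitted a background mean of -611, against -9.40 to -2.85 on the other arrays. With those backgrounds replaced by the array's median 17997 passed, with a shift of -0.11 and 36.0% higher. Stricter thresholds left fewer probes, 7477 with a 2-fold change and 7037 at an adjusted p of 0.01. With the mean of a gene's probes 9575 genes passed of 22944, which are fewer units. Within slide 1 3268 probes passed and within slide 2 283, with 2 arrays per group in place of 4. The replicate numbers of the labels share only a number: deviations from the group means correlated by -0.018 to 0.081 within a number, and of the tumors only eye tumor 1 correlated best with the normal eye of its own number. With that number as a block 12272 probes passed, 11755 of them shared.

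The number of lists that passed (19) was 17 to 19 when arrays were left out and 14 to 22 under the other settings, but 0 with an estimated correlation. The mean of the Hedgehog targets was 1.94 to 2.29 when arrays were left out, 0.63 with normexp and 0.96 with normexp after the replacement. With an estimated correlation it was 2.14 with an adjusted p of 0.525, since that setting changes the test alone. With normexp the direction turned for dbx1b (-0.45), disp1 (-0.44), fshb (-0.34), hoxb5b (-0.35), lhb (-0.71, and -0.00242 after the replacement), nkx2.2b (-0.38) and scn4ab (-0.20), and with the mean of all probes for mxc (0.86). None of these passed there. Of the genes turned by normexp, only lhb was still turned after the replacement. Apart from that replacement, the cause was not tested. Of 125 named genes, 124 or more kept their direction and side of the threshold with quantile normalization, scaling by the median, the deposited table and array weights. The number was 123 with the slide as a block, 120 with the replicate number as a block, 76 with normexp, 68 within slide 1 and 20 within slide 2. Of the 120 named genes that passed, 7 lost the call without at least 1 array. Signal near background limits the folds of the genes given as a bound.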

Other observations

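The lists for brain regions, the pituitary and motile cilia were written after the largest changes had been seen and before their own test; the tests of the Hedgehog targets without regional genes, of the hormones without the filter, of the globins and of adjacent genes were chosen after the result was seen.

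Genes of motile cilia rose in the tumors beyond foxj1a. Of 21 measured genes of a motile cilia list from which genes already seen were left out, 16 rose, 1 fell and 4 did not pass (17 rose and 2 fell adjusted over the list alone), with a mean log2 change of 1.64 (adjusted p = 3.80e-06; adjusted p = 0.350 with an estimated correlation). The mean was 1.19 to 2.27 in the 4 tumors. Examples chosen after their values were seen were the cilia regulators foxj1b (3.36 ± 0.56) and rfx2 (2.45 ± 0.32) and the axonemal gene efhc2 (3.18 ± 0.44). Telencephalon genes numbered 7 up, 2 down and 6 not passed of 15 (adjusted p = 0.122), with emx3 (2.35 ± 0.23) and dlx5a (2.49 ± 0.43) up, hypothalamus genes 3 up, 1 down and 10 not passed of 14 (adjusted p = 0.279), with otpa up (3.48 ± 0.69), and genes of the midbrain and cerebellum 5 up, 1 down and 7 not passed of 13 (adjusted p = 0.0992), with zic1 up (2.45 ± 0.17). The mean of the hypothalamus list was 1.86 and 0.99 in eye tumors 1 and 2, but 0.13 and 0.10 in eye tumors 3 and 4. Of the pituitary hormones other than gh1, 2 of 4 measured rose (adjusted p = 0.215). Pituitary regulators numbered 1 up, 1 down and 6 not passed of 8 (adjusted p = 0.811), and hindbrain and spinal cord genes 2 up, 3 down and 7 not passed of 12 (adjusted p = 0.905). These lists did not pass, with the estimated correlation either.

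The rises of gh1, avp, oxt, dlx1a and sp9 raise the hypothesis that the dissected tumors may have held tissue of the pituitary or brain. Pituitary tissue brings its other hormones too. Without the filter on dim probes, 2 of the 9 others with a probe (fshb and pomcb) were at least 4-fold higher past the threshold, against at least 11538-fold for gh1. The hormone genes prl, cga and smtla were not above background on any array. That speaks against pituitary tissue as the source of gh1 only if their probes respond, which no array here shows. Some hormones were seen in the tumors: pomcb was above background in 3 tumors and tshba in 2, both in 0 normal eyes, fshb rose by 2.04 ± 0.42 and lhb by 1.33 ± 0.27. With normexp fshb and lhb turned to -0.34 and -0.71, and after the replacement of far local backgrounds to 0.35 and -0.00242, none of which passed. The gene pomca did not pass (1.71, with an SD of 2.53 in the tumors, adjusted p = 0.238). Its log2 signal was -1.88 and -2.24 in eye tumors 1 and 2, but -5.97 and -6.83 in eye tumors 3 and 4, against a mean of -5.94 in the normal eyes. In eye tumors 1 to 4 pomcb was at 0.49, -2.53, -4.84 and -6.75, and gh1 at 7.53, 6.31, 6.95 and 6.25. Thus gh1 varied far less across the tumors than pomca and pomcb did, while fshb was highest in eye tumor 4 (-3.84). Of the measured genes of the hindbrain and spinal cord list 16.7% rose (Wilson 95% interval 4.70 to 44.8), where brain tissue of all regions was expected to raise 50%. That leaves such tissue open. Of the 28 members with a probe 12 were measured, and 9 of these were above background in normal eyes, which would hide a small share. The 3 others passed the filter only by their signal in all 4 tumors. The filter thus favored a rise among them, and no conclusion is drawn from the 2 that rose. These 2 were hoxb5b (at least 3.28-fold) and dbx1b (at least 2.68-fold), both named after their values were seen. Both were turned by normexp (-0.35 and -0.45, not passed), but not after the replacement. The shares were 21.4% (7.57 to 47.6) for the hypothalamus and 46.7% (24.8 to 69.9) for the telencephalon, without the genes already seen. Of all genes tested, 4571 of 22944 rose, a share close to those of the hypothalamus and of the hindbrain and spinal cord. No difference between regions was tested, and brain tissue cannot be told apart from tumor cells with brain genes. Ciliated cells are a candidate source that the values go with, since 76.2% of the 21 measured genes of the motile cilia list rose. That list held 44 genes, of which 24 had a probe. Next to gh1 on chromosome 3, ifnphi3 and rdm1 (adjusted p = 6.43e-05) rose as well, and a local effect such as that of an inserted transgene could not be told apart from separate changes: of the 7 genes within 200 kb other than gh1 and ifnphi3, 28.6% rose at least 2-fold. These were rdm1 and scn4ab (1.14 ± 0.33), while arhgap27l fell (-1.11 ± 0.22, adjusted p = 0.00725), named after its value was seen. The call of scn4ab was lost without normal eye 2 or 4 or eye tumor 1, 2 or 4. With normexp scn4ab turned to -0.20 and did not pass, but it was not turned after the replacement. By representative probes, 1 of 21064 runs of 3 adjacent genes, the run at gh1 itself, had a smallest log2 change as large as 5.59. That rests on the choice of probe: another probe of rdm1 changed by 3.76, and the highest other run had 5.25. The labels give no insertion site.

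The rise of the Hedgehog target list could rest on genes that also mark brain regions, such as nkx2.2a, foxa2 and olig2. Without these, 5 of the 6 targets left had risen, with a mean log2 change of 0.79 and an SE over genes of 0.30 (adjusted p = 0.0299, and 0.525 with an estimated correlation). In the main fit the rise thus did not rest on regional genes alone, though these carry most of its size and the margin is small. The SE treats the 6 genes, read on the same arrays, as independent. The values do not show what raised the targets left. When each array was left out the mean was 0.62 to 0.90 and 2 to 4 of the 6 passed, with hhip and mycn among those lost. Within slide 1 the mean was 0.73 and 1 passed, and within slide 2 it was 0.85, where 0 passed and the list's call was lost (adjusted p = 0.0604). With normexp it was 0.28 with an SE of 0.31 and 1 passed, and after the replacement 0.48 with an SE of 0.24 and 4 passed. Whether the smo probes read the transgene was not tested.

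The fall of adult globin genes could reflect fewer red blood cells in the tumors, or globin copies that differ between the fish strains. A lower share of red cells alone would lower the adult globins about as much as other red cell genes; of 5 adult globin names 3 (ba2, hbaa2 and hbba2) had fallen by over 2 combined SE more than gata1a, the lowest of those by representative probe, and hbaa1 and hbba1 had not. Since ba2 is also an older name of hbba2, these may not be 5 separate genes. Against the lowest single probe, 1 of alas2 (-3.46 ± 0.50), ba2 still lay lower by 3.23 combined SE, or 9.42 at its second probe, and hbaa2 by 3.84. The gap of hbba2 was 1.32 by its representative probe and 8.87 by another, while hbaa1 and hbba1 did not lie lower. The gene alas2, singled out after its values were seen, fell by less at its brightest probe (1.997 ± 0.53 on the log2 scale), where its call was lost without normal eye 1 (adjusted p = 0.0508). The smallest gap between ba2 or hbaa2 and hbaa1 or hbba1 was 3.47 combined SE, as variants under some probes would give, but that test was chosen after the result was seen. Every combined SE treats the genes compared, read on the same arrays, as independent. The explanations cannot be told apart, since strain and tumor go together in this design and probes of similar globins may bind each other's transcripts.

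Other splits of the 8 arrays into 4 and 4 tested whether chance could give the results. The real split gave 15331 probes and the highest other split 3, so that 1 of 35 splits gave as many. For the mean of the Hedgehog targets the real value was 2.14 and the highest other 1.3001, again 1 of 35. That is the smallest share that 35 splits can give, so chance is not excluded by it. For the number of lists, 7 of the 35 splits gave at least the real 19, the highest other 22, so chance cannot be excluded for that number. Every other split mixes tumors with normal eyes. A real difference then adds to the spread within the groups and remains in part between them, so the other splits do not show chance alone.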
